A study of Homo sapiens with 22 samples.

How the data were processed

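CUT&Tag libraries of MCF7 cells were measured in 8 groups: AF9, Flag-AF9WT, Flag-AF9F28R, Flag-AF9G77A, H3K9la and H3K9ac with 3 libraries each, and Flag-vector and Flag-KLF2 with 2 libraries each. The antibodies were not given in the sources used here, so the AF9 group was read as a profile of AF9 and the Flag groups as profiles of the tagged proteins. The labels do not say that replicates are separate cultures, so every permutation p-value measures only the spread between these samples. The p-values of Fisher's exact tests run over genes, which are not independent replicates, and measure no spread between samples.

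Per the submitters' processing notes, BWA 0.7.15, SAMtools 1.3.1, Picard 1.107, deepTools 3.3.0 and MACS2 2.1.2 were used with the hg38 build, with no role or setting stated. The authors deposited 1 peak list per library, 616038 peaks in all, with no read counts. The deposited score of each peak was 10 times its -log10 q, as a whole number. The deposited fold enrichment is a ratio of the pileup at the summit to the local background, on a linear scale, and comes from the authors' peak caller. The authors' -log10 p values test the summit against the same background, and their -log10 q values are those p-values adjusted within a library. The deposited summit position is given in bp from the start of the peak. No deposited list held a peak with q above 0.05.

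Peaks that touched were merged within a library, and chromosomes 1 to 22 and X were kept, which left out 725 peaks. Peaks of all libraries of a group were joined where they touched, and a region was a joined stretch that peaks of at least 2 libraries overlapped. Parts of a region can therefore be covered by a single library. Overlap meant at least 1 bp. Chance overlap was measured with 100 circular shifts of the overlapping set along the chromosomes.

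The lists give no depth, so a relative depth was recovered from them. For each peak the fold enrichment and the -log10 p were solved for a whole-number pileup and its background. The misfit allowed was 0.001 times the deposited -log10 p, which gave a solution for 97.0% to 100.0% of the peaks of a list. The lowest background shared by at least 10 peaks, called the background pileup, served as the relative depth of a library. It ran from 0.06 in a Flag-vector library to 1.29 in an H3K9la library. It ranks libraries by depth and gives no number of reads, so no counting interval could be attached to a value.

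No genome came with the lists, and the gene table held gene starts and ends of GRCh38.p14 with no strand. A planned promoter window was therefore replaced by a gene-end window, 1 kb to each side of either end of 19970 protein-coding genes. A gene had a gene-end peak in a library when any peak overlapped that window, and a group had it when at least 2 libraries did. The window covers only the outermost annotated ends. A promoter further inside a gene is missed, so the lack of a gene-end peak does not mean the lack of a promoter peak. Peaks were also placed by their midpoints at a gene end, in a gene body or outside genes, in place of the planned exon and intron classes. All 255 of 255 listed genes were matched to the table. A planned search for the KLF motif needs genome sequence and was not analysed here.

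The 14 gene lists were fixed before the data were examined: KLF family transcription factors, AF9 partners and related complexes, glycolysis and lactate, acyl writers and erasers, EMT and invasion, epithelial adhesion, metastasis suppressors, luminal and estrogen response, KLF2 targets known from other cells, cell cycle and proliferation, HOXA cluster, cytosolic ribosomal proteins, basal and mesenchymal breast, and genes of other tissues. Named genes followed a rule written at the same time. It takes KLF2 and MLLT3 in every library, and up to 4 members of each list whose calls differ most between the groups compared. It also takes the 10 genes with a gene-end peak in every library of one group and none of the other, ranked by the mean percentile of -log10 p within the libraries (5 where Flag-AF9WT was set against 1 mutant), and the 10 genes highest by that rank with a peak in every AF9, Flag-AF9WT, Flag-KLF2 and H3K9la library and in no Flag-vector library. The text gives part of what the rule selects.

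Differences between groups of libraries were tested with two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment within each family of comparisons. With 3 libraries against 3, or 3 against 2, the smallest p these tests can give is 0.1, and with 3 against 6 it is 0.0119. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests adjusted over 112 tests, and again among genes with an H3K9ac gene-end peak. Co-occupancy of genes by Flag-KLF2 and AF9 was given as a Mantel-Haenszel odds ratio within strata of H3K9ac, with a 95% interval over genes, which are not independent replicates.

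Batches were read from the peak names. The first batch held replicate 1 of AF9, Flag-AF9WT, both mutants, H3K9la and H3K9ac. The second held replicate 2 of Flag-AF9WT, Flag-AF9G77A and H3K9ac, and the third held Flag-AF9WT replicate 3 with Flag-AF9F28R replicate 2. Flag-KLF2 replicate 2 stood alone. An undated set with its own number format held AF9 replicates 2 and 3, H3K9la replicates 2 and 3, H3K9ac replicate 3, Flag-KLF2 replicate 1 and replicate 3 of both mutants, and both Flag-vector lists formed another undated set. Peak names of AF9 replicate 1, H3K9ac replicates 1 and 2 and H3K9la replicate 1 also carried the Flag-AF9WT name. The replicate numbers did not pair libraries across groups, with correlations from -0.12 to 0.15 over 45 pairs of lists, so no replicate block was used in the main tests. The 9 pairs above 0.1 were all of the same batch, and the main tests do not account for batch.

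Alternatives planned before the data were examined were a stricter peak threshold (-log10 q of at least 5), the same number of peaks (4117) in every list but the 2 Flag-vector lists, which are shorter and stayed whole, removal of peaks at Flag-vector peaks, overlap over 50% of the shorter region, regions required in every library, a 2.5 kb window, all sequences, unmerged peaks, a replicate block and leaving out each library in turn. Alternatives added after the data were seen left out replicate 3 of both mutants, thinned every list but the shallower Flag-vector lists to 1 depth (background pileup 0.2187), left out peaks at MLLT3 and KLF2, or used only the gene end with the stronger H3K9ac peak. Under every setting that changed the lists, the regions of each group were called again from the changed lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

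The steps were tested on simulated data made as peak lists. Whole-number pileups were recovered for 99.9% of 3995 simulated peaks at a background of 0.06, and 94% of 200 planted lost regions were called lost, with 429 others, among 58230. The simulated groups had 3 libraries each and equal detection rates. That count therefore cannot show how many regions are called lost when a group is shallower, as the mutants were. Random lists of 20 genes passed an unadjusted p of 0.05 in 3.25% of 400 draws.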

Results

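CUT&Tag, in which a tethered transposase cuts chromatin beside an antibody-bound protein, was applied to MCF7 cells, an estrogen receptor-positive human breast cancer line. The identity of the line was not tested here. H3K9ac had gene-end peaks at 11 of 20 luminal and estrogen response genes, 11 of 18 epithelial adhesion genes and 18 of 22 EMT and invasion genes. Over all protein-coding genes the share with one was 60.3%. CDH1, ESR1, the estrogen receptor gene, TFF1, PGR, SPDEF and AGR2 had a gene-end peak in 0 of 3 H3K9ac libraries, and GATA3 in 1 of 3. KRT8, KRT18, FOXA1, VIM, ZEB1 and AXL had one in 3 of 3, all genes named after their values were seen. AF9, encoded by MLLT3, reads acylated histone lysines through its YEATS domain, and both mutants, F28R and G77A, change a residue of that domain. The title of the series names AF9, KLF2 and histone lactylation, and the groups ask where AF9 and KLF2 sit relative to lactylated (H3K9la) and acetylated (H3K9ac) histone H3, and whether the AF9 mutants still sit there. The 22 libraries held 24131 to 32503 merged peaks for AF9, 30483 to 43842 for Flag-AF9WT, 7904 to 35730 for Flag-AF9F28R, 4117 to 31388 for Flag-AF9G77A and 34855 to 45096 for Flag-KLF2. H3K9la libraries held 29699 to 37295 peaks, H3K9ac libraries 41221 to 46935, and the Flag-vector control libraries 942 and 1113. Relative depth, given as the background pileup, averaged 0.432 ± 0.260 (SD, n = 3) for AF9, 0.856 ± 0.104 (n = 3) for Flag-AF9WT, 0.430 ± 0.177 (n = 3) for Flag-AF9F28R and 0.271 ± 0.0745 (n = 3) for Flag-AF9G77A. It was 0.564 ± 0.161 (n = 2) for Flag-KLF2, 0.892 ± 0.349 (n = 3) for H3K9la, 1.1 ± 0.0525 (n = 3) for H3K9ac and 0.0622 ± 0.00304 (n = 2) for Flag-vector, so Flag-AF9WT was 1.99 times as deep as Flag-AF9F28R, 3.16 times as deep as Flag-AF9G77A and 13.8 times as deep as the control. The shallow control lists cannot show a weak background signal.

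KLF2, a zinc-finger transcription factor gene at chromosome 19, 16324826 to 16328685 (hg38), had a peak over its lower-coordinate end in all 3 AF9, all 3 Flag-AF9WT, all 3 H3K9la and all 3 H3K9ac libraries, and in neither Flag-vector library. The fold enrichment of that peak over local background, as the authors gave it, was 7.98, 11.6 and 7.44 in AF9, 6.01, 4.46 and 6.01 in Flag-AF9WT, 4.92, 5.93 and 4.91 in H3K9la, and 5.69, 5.92 and 7.65 in H3K9ac. Among the mutants it was present in replicates 2 and 3 of Flag-AF9F28R (8.93 and 8.59) and replicate 3 of Flag-AF9G77A (5.62). In Flag-AF9G77A replicate 2 a peak (5.80) lay just inside the gene, at 16324893 to 16325185, and replicate 1 of each mutant, the shallowest library of its group, had none. Both Flag-KLF2 libraries had their strongest peak of the genome inside KLF2, at 16324699 to 16326196 and 16325022 to 16326125, over the gene that the tagged construct encodes. A gene-end peak at MLLT3, the AF9 gene at chromosome 9, 20341669 to 20622499, was present in 1 of 3 AF9, 1 of 3 Flag-AF9WT, 1 of 3 Flag-AF9F28R, 2 of 2 Flag-KLF2 and 2 of 3 H3K9ac libraries, and in no Flag-AF9G77A, H3K9la or Flag-vector library. No test was run on single genes.

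**Figure D1:**
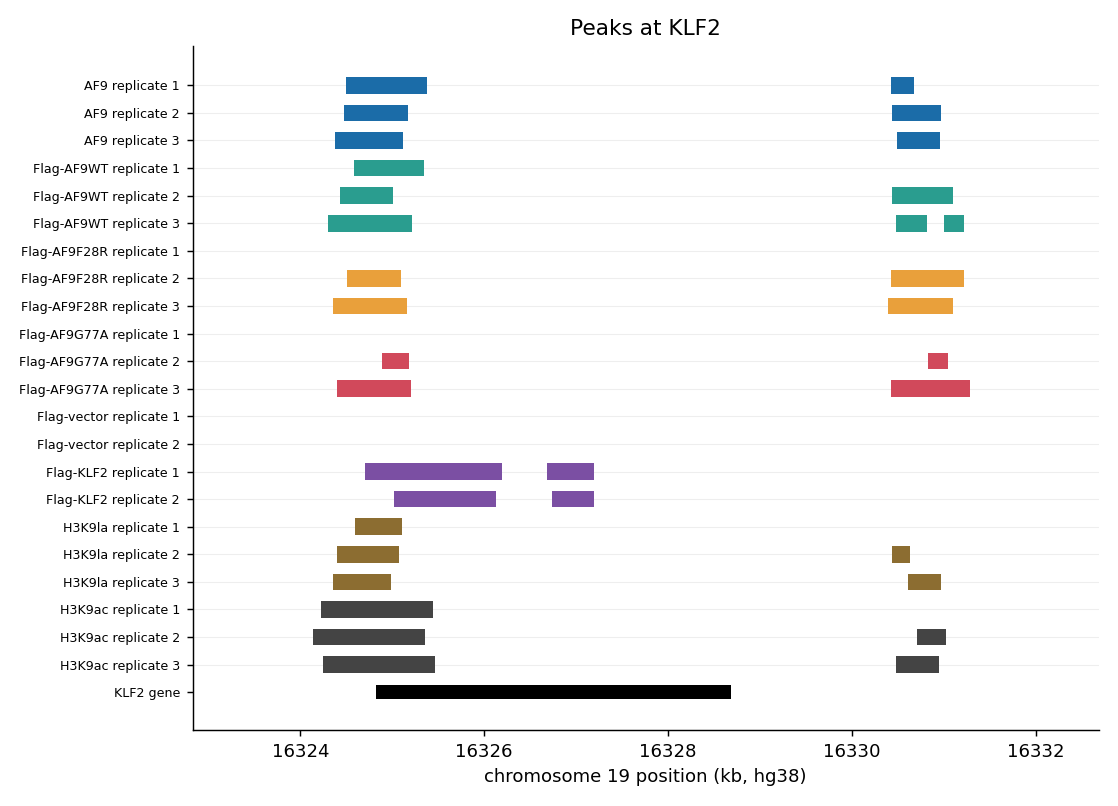
Peaks at KLF2 on chromosome 19, with position in kb (hg38) on the horizontal axis and 1 line per library, where each bar is a deposited peak after merging and the black bar is the gene. A peak covers the lower-coordinate end in all 3 AF9 and all 3 Flag-AF9WT libraries, in 2 of 3 Flag-AF9F28R and 1 of 3 Flag-AF9G77A libraries and in neither Flag-vector library.

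AF9 sat mainly where both histone marks lay. Of 22980 AF9 regions, 15988 (69.6%) overlapped regions of both marks, 3152 (13.7%) H3K9ac regions alone, 1429 (6.22%) H3K9la regions alone and 2411 (10.5%) neither. H3K9la regions overlapped 75.8% of AF9 regions and H3K9ac regions overlapped 83.3%, against 1.36% and 2.24% after circular shifts. An AF9 library overlapped 75.8% ± 5.20 (SD, n = 3) of the 20834 regions with both marks, 25.7% ± 5.70 of the 5753 regions with H3K9la alone and 26.8% ± 12.5 of the 14549 regions with H3K9ac alone. A Flag-AF9WT library overlapped 77.8% ± 4.16, 18.6% ± 3.97 and 41.9% ± 6.96 (n = 3) of the same regions, and a Flag-vector library 1.63% ± 0.221, 1.77% ± 0.172 and 0.278% ± 0.0340 (n = 2). The share at regions with H3K9la alone minus that at regions with H3K9ac alone was -1.08 points (SD 17.9, n = 3) in AF9, within the spread between replicates, and -23.3 points (SD 5.45, n = 3) in Flag-AF9WT, beyond it. H3K9la replicates 2 and 3 and H3K9ac replicate 3 came from the undated set. That set held AF9 replicates 2 and 3 and no Flag-AF9WT library, so mark and batch cannot be told apart in these differences. When single libraries were left out, the AF9 value ran from -15.2 (without H3K9la replicate 3) to 9.25 (without AF9 replicate 1), and was also above 0 without H3K9la replicate 1 or H3K9ac replicate 2 or 3, while the Flag-AF9WT value ran from -27.7 to -20.2. With the same number of peaks in all lists but Flag-vector these differences were 22.4 and -10.7 points, and the AF9 value was 6.90 with only peaks of -log10 q of at least 5 and 1.14 at 1 depth. Regions with a single mark were also weaker in their own lists: the median percentile of -log10 p was 37.6 ± 3.05 (n = 3) for H3K9la alone against 67.8 ± 3.90 where H3K9ac was present, and 43.9 ± 0.696 for H3K9ac alone against 70.3 ± 2.56 where H3K9la was present.

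**Figure D2:**
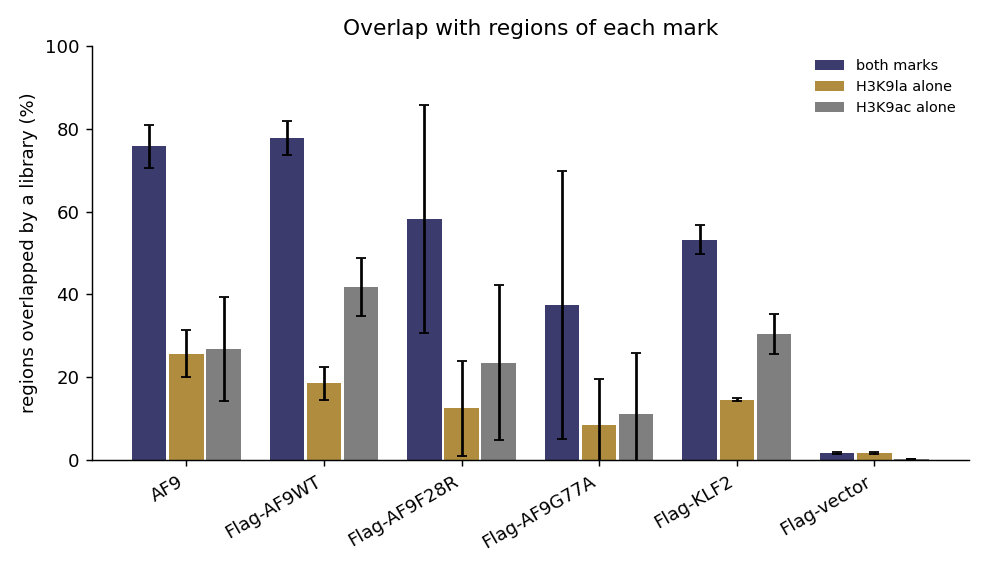
Share of regions overlapped by a library (percent, vertical axis) for regions with both marks, H3K9la alone or H3K9ac alone, by group, where bars are means and error bars SD over 3 libraries (2 for Flag-KLF2 and Flag-vector), with bars that would pass below 0 ended at the axis. AF9 libraries overlapped 75.8% of regions with both marks, Flag-AF9WT 77.8% and Flag-vector 1.63%.

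AF9 peaks had a higher mean gene-end share than peaks of either mark, by differences that depended on the peak threshold. The gene-end share was 30.5% ± 0.379 (SD, n = 3) for AF9, 24.1% ± 0.543 (n = 3) for H3K9la, 26.4% ± 1.80 (n = 3) for H3K9ac and 12.1% ± 3.56 (n = 2) for Flag-vector. The differences were 6.36 points from H3K9la and 4.09 points from H3K9ac, each with p = 0.1 in a two-sided exact permutation test, the smallest it can give, and an adjusted p of 0.25 over 5 comparisons. Within the first batch the shares were 30.8% for AF9, 24.2% for H3K9la and 27.9% for H3K9ac, and in the undated set they were 30.1% and 30.5%, 23.5% and 24.6%, and 24.4%. With only peaks of -log10 q of at least 5 the differences were 4.10 points from H3K9la and 1.08 from H3K9ac (exact p = 0.3 and 0.8), and with a 2.5 kb window that from H3K9ac was 2.39 (exact p = 0.2). At 1 depth the difference from H3K9la was 2.46, and with the same number of peaks in all lists but Flag-vector it was 4.07. The difference from H3K9ac turned to -30.6 points with the same number of peaks in all lists but Flag-vector and to -12.9 points at 1 depth.

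Flag-AF9WT held AF9 regions, H3K9la regions and H3K9ac regions at higher shares than the mean of either mutant, but the mutant libraries differed widely among themselves. Of the AF9 regions, a Flag-AF9WT library overlapped 74.0% ± 4.13 (SD, n = 3), a Flag-AF9F28R library 59.6% ± 30.4 (n = 3), a Flag-AF9G77A library 39.3% ± 36.0 (n = 3) and a Flag-vector library 1.78% ± 0.178 (n = 2). Replicates 1, 2 and 3 held 27.5%, 63.3% and 87.9% in Flag-AF9F28R and 14.4%, 22.9% and 80.5% in Flag-AF9G77A, against 69.6%, 74.6% and 77.8% in Flag-AF9WT. H3K9la regions were overlapped at 64.4% ± 4.08 in Flag-AF9WT, 48.0% ± 24.0 in Flag-AF9F28R and 30.6% ± 27.5 in Flag-AF9G77A (n = 3 each), and H3K9ac regions at 63.0% ± 5.28, 44.0% ± 23.8 and 26.6% ± 25.0. Of the peaks of a library, 84.2%, 67.9% and 57.5% lay in AF9 regions in replicates 1, 2 and 3 of Flag-AF9F28R. The shares were 82.6%, 79.6% and 60.9% in Flag-AF9G77A, 55.5%, 41.4% and 49.2% in Flag-AF9WT and 47.0% and 34.6% in Flag-vector. On average 43.2% of Flag-vector peaks lay in H3K9la regions and 38.2% in H3K9ac regions, against 48.4% and 66.4% for Flag-AF9WT. The control lists, of 942 and 1113 peaks, were thus often at these sites but could overlap only a small share of them. Within each group the share of peaks in AF9 regions fell as the number of peaks rose.

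None of these differences passed a two-sided exact permutation test. For AF9 regions the difference was 14.5 points from Flag-AF9F28R (exact p = 0.6, adjusted 0.6), 34.8 from Flag-AF9G77A (exact p = 0.4, adjusted 0.5), 24.6 from both mutants (exact p = 0.31, adjusted 0.5) and 72.2 from Flag-vector (exact p = 0.1, adjusted 0.25). For H3K9la regions it was 16.4, 33.8 and 25.1 points from Flag-AF9F28R, Flag-AF9G77A and both (exact p = 0.4, 0.2 and 0.155, adjusted 0.4, 0.3 and 0.3), and for H3K9ac regions 19, 36.4 and 27.7 points (exact p = 0.3, 0.1 and 0.0714, adjusted 0.36, 0.3 and 0.3). Peaks per library differed by 15244 from Flag-AF9F28R, 23027 from Flag-AF9G77A, 19135 from both and 36140 from Flag-vector (exact p = 0.2, 0.2, 0.0714 and 0.1, adjusted 0.2 for each). Flag-AF9WT and Flag-vector shared no batch, so group and batch cannot be told apart there. Within the 3 batches that held Flag-AF9WT beside a mutant, the share of AF9 regions was 2.53 and 4.85 times as high as in Flag-AF9F28R and Flag-AF9G77A replicate 1, 3.25 times as high as in Flag-AF9G77A replicate 2 and 1.23 times as high as in Flag-AF9F28R replicate 2. The mean within-batch difference was 38.3 points for AF9 regions, 35.3 for H3K9la regions, 37.2 for H3K9ac regions and 25479 peaks, each with a within-batch permutation p of 0.0833, the smallest that 12 arrangements can give. In the same pairs Flag-AF9WT was 3.47, 3.59, 3.40 and 1.76 times as deep.

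At 1 depth the AF9 regions were called again from the thinned AF9 lists. The difference in AF9 regions was then -13.9 points from Flag-AF9F28R, -0.445 from Flag-AF9G77A and -7.19 from both mutants. Shares by replicate were taken over the AF9 regions of the full lists instead, so they do not average to these differences. Of those, thinned replicates 1, 2 and 3 held 27.2%, 45.4% and 72.0% in Flag-AF9F28R and 14.3%, 22.6% and 71.4% in Flag-AF9G77A. Flag-AF9WT held 32.7%, 33.1% and 42.4%. Replicates 1 and 2 of Flag-AF9G77A thus stayed below every Flag-AF9WT library, and replicate 3 alone brought the Flag-AF9G77A mean up. The difference in H3K9la regions was -9.91, 3.66 and -3.12, in H3K9ac regions -7.10, 9.92 and 1.4, and in peaks per library -2607, 426 and -1090. With the same number of peaks in all lists but Flag-vector it was -10.2, -3.05 and -6.61 in AF9 regions, while it stayed positive in H3K9la regions (2.69, 8.54 and 5.61) and in H3K9ac regions (14.9, 23.4 and 19.2). There the exact p for both mutants was 0.0476 and 0.0119, with adjusted values of 0.12 and 0.0714. Without Flag-AF9F28R replicate 1 the difference from that mutant was -1.58 points, and without replicate 3 it was 28.6 from Flag-AF9F28R and 55.4 from Flag-AF9G77A. Without Flag-AF9G77A replicate 1 the difference from Flag-AF9G77A was 22.3. Without Flag-AF9F28R replicate 1 the difference from that mutant was 3.43 points in H3K9la regions, 6.13 in H3K9ac regions and 8234 peaks, and without its replicate 3 it was 27.1 and 29.6 points in the marks. With only peaks of -log10 q of at least 5, peaks per library differed by 5352 from Flag-AF9F28R, 11117 from Flag-AF9G77A, 8234 from both and 20012 from Flag-vector. From Flag-vector the difference at 1 depth was 11335 peaks. Over AF9 regions called again under each setting it was 38.3 points at 1 depth and 41.4 points with the same number of peaks in the other lists. The AF9 regions themselves came in 2 of 3 libraries from the undated set that held replicate 3 of both mutants.

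**Figure D3:**
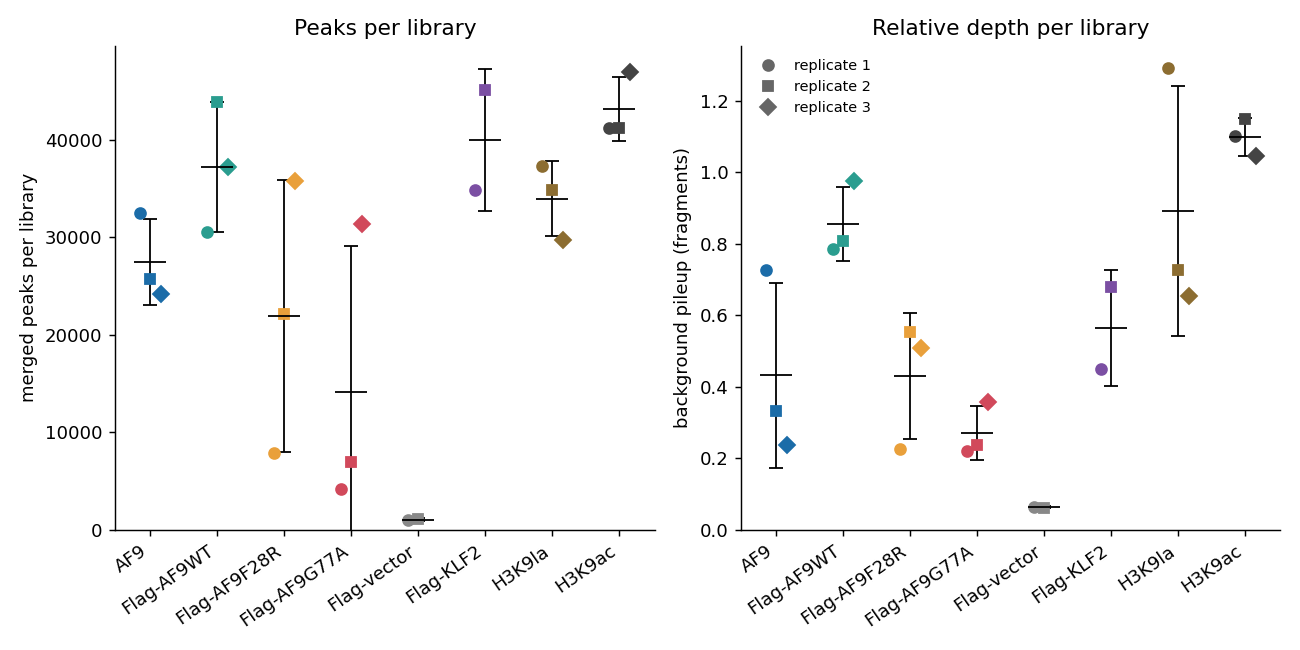
Merged peaks per library (left, count) and background pileup per library (right, fragments) by group, where points are libraries, long horizontal lines are means and error bars are SD, with bars that would pass below 0 ended at the axis. Flag-AF9G77A libraries range from 4117 to 31388 peaks at a background pileup of 0.219 to 0.356.

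**Figure D4:**
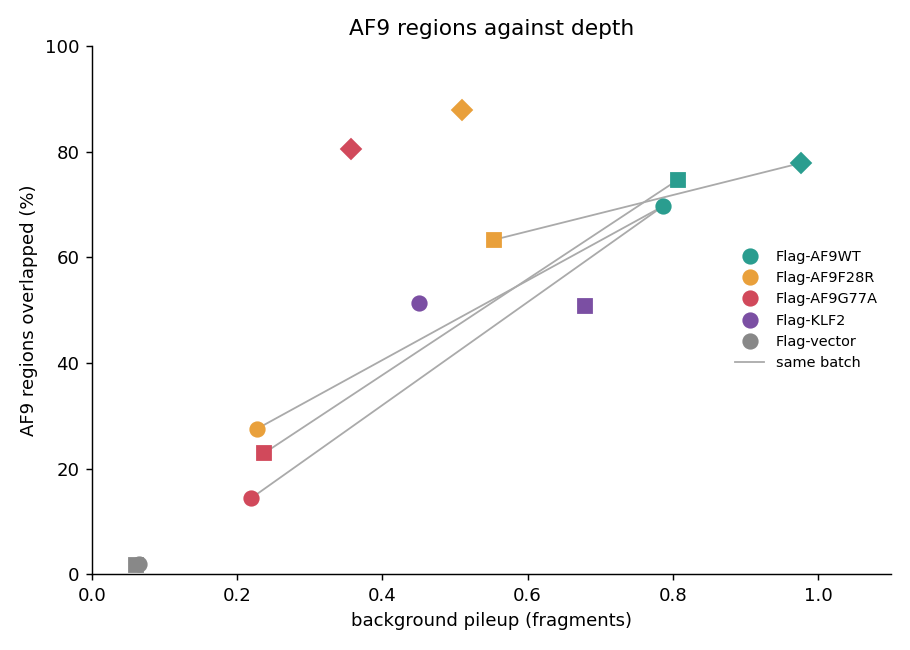
Share of AF9 regions overlapped (percent, vertical axis) against background pileup (fragments, horizontal axis), where points are libraries, circles, squares and diamonds are replicates 1, 2 and 3, and gray lines join Flag-AF9WT to a mutant library of the same batch. Replicate 3 of the mutants lies at 87.9% and 80.5%, above replicates 1 and 2.

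Regions here were blocks of joined peaks of all Flag-AF9WT and mutant lists. Blocks in every Flag-AF9WT and no mutant library were shorter than all blocks in every Flag-AF9WT library. They also lay less often at gene ends or in AF9 regions. A block that more lists hold joins more peaks, so part of the difference in width and overlap is fixed by construction. There were 1894 regions in every Flag-AF9WT library and in no mutant library, against 7 in the reverse direction. Of the 1894, 52.6% lay outside genes, 10.5% at gene ends, 15% in AF9 regions, 24.4% in H3K9la regions and 50.4% in H3K9ac regions, with a median width of 606.5 bp. Of all 19639 regions in every Flag-AF9WT library, 33.2% lay outside genes, 38.1% at gene ends, 71.9% in AF9 regions, 71.2% in H3K9la regions and 86.6% in H3K9ac regions, with a median width of 930 bp. Of the 2307 regions in every Flag-AF9WT and every mutant library, 50.1% lay at gene ends, 93.7% in AF9 regions, 89.6% in H3K9la regions and 93.8% in H3K9ac regions, with a median width of 1252 bp. Against Flag-AF9F28R alone the counts were 2186 and 28, and against Flag-AF9G77A alone 4394 and 37. Leaving out single libraries took these reverse counts as high as 509 and 157. Without replicate 3 of the mutants the counts of Flag-AF9WT regions were 4659, 4746 and 13538 (both mutants, Flag-AF9F28R and Flag-AF9G77A). The count against both was 4073 without Flag-AF9WT replicate 1 and 3367 without replicate 3, and that against Flag-AF9F28R 4546 and 3763. Against Flag-AF9G77A it was 7734 without Flag-AF9WT replicate 1. At 1 depth Flag-AF9WT regions and the reverse numbered 85 and 109, 144 and 414, and 265 and 238.

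At genes, 168 had a gene-end peak in every Flag-AF9WT library and in no mutant library, and 0 the reverse. The highest-ranked were PCSK6, a proprotein convertase (chromosome 15, 101303933 to 101489707), KIRREL1, an adhesion molecule (chromosome 1, 157993645 to 158100262), SAMD13, SPRR1B, a cornified envelope protein, C11orf96, NUDT12, the neighbouring imprinted genes PEG10 and SGCE, which share a peak, PHKA1 and MED4, a Mediator subunit. Their mean percentile of -log10 p in Flag-AF9WT ran from 69.5 (MED4) to 81.6 (PCSK6), so none was among the strongest peaks. KLF2 had a peak in 3 of 3 Flag-AF9WT and 4 of 6 mutant libraries. Against Flag-AF9F28R alone there were 217 genes, led by LCA5 and including the arginine methyltransferase gene PRMT6, and 1 gene the reverse, MRGBP, but the reverse numbered 34 without Flag-AF9F28R replicate 1 and 11 without Flag-AF9WT replicate 3. Against Flag-AF9G77A alone there were 941, led by PRSS12, DIP2B, GOSR2, MMADHC and FBXW4, and 0 the reverse. Without replicate 3 of the mutants there were 732, 744 and 5293 such genes, and at 1 depth 21 against 37 the reverse, 50 against 155 and 148 against 50. With the same number of peaks in all lists but Flag-vector there were 159 against 36, 225 against 80 and 457 against 92. The 168 became 348 without Flag-AF9F28R replicate 3, 297 without Flag-AF9WT replicate 1, 255 without Flag-AF9F28R replicate 2 and 253 without Flag-AF9WT replicate 2, and the 217 became 362 and 347 without Flag-AF9WT replicate 1 and Flag-AF9F28R replicate 2. With 3 libraries against 3, the real grouping is 1 of 10 possible splits.

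Members of all 14 gene lists with a gene-end peak were more numerous in Flag-AF9WT libraries than in mutant libraries on average, and no list passed after adjustment. All genes with a gene-end peak fell alike, from 10396 ± 705 per Flag-AF9WT library (SD, n = 3) to 8055 ± 3370 in Flag-AF9F28R and 4930 ± 3779 in Flag-AF9G77A (n = 3 each). Members followed the single libraries, as with KLF family genes at 4, 9 and 10 in replicates 1, 2 and 3 of Flag-AF9F28R and 1, 6 and 10 in Flag-AF9G77A, so the counts say little about the lists themselves. Epithelial adhesion genes came nearest, with 9.67 ± 0.577 of 18 in Flag-AF9WT (SD, n = 3) and 4.67 ± 1.97 in the mutants (n = 6), an exact permutation p of 0.0238 and an adjusted p of 0.333 over the 14 lists. ESRP2, an epithelial splicing regulator, had a peak in 3 of 3 Flag-AF9WT and 0 of 6 mutant libraries, and EPCAM, an epithelial surface protein, in 3 of 3 and 1 of 6. EMT and invasion genes numbered 15.3 ± 0.577 of 22 against 9 ± 4.94 (LOX, a collagen cross-linking enzyme, 3 of 3 and 1 of 6, and TWIST1 and CDH2 3 of 3 and 2 of 6). Glycolysis and lactate genes numbered 17.7 ± 0.577 of 21 against 12.3 ± 5.61 (PFKL, a phosphofructokinase, 3 of 3 and 1 of 6, and HK2, a hexokinase, 3 of 3 and 2 of 6). Acyl writers and erasers numbered 17 ± 1.73 of 19 against 12 ± 4.60 (the acetyltransferase gene KAT2B, 3 of 3 and 1 of 6), and AF9 partners 16.7 ± 3.06 of 20 against 12.8 ± 6.37. KLF family genes numbered 9.67 ± 1.15 of 17 against 6.67 ± 3.67, and KLF2 targets known from other cells 8.67 ± 0.577 of 15 against 5.33 ± 3.72. Metastasis suppressors numbered 10.7 ± 1.53 of 16 against 7.67 ± 3.44 (MAP2K4, 3 of 3 and 2 of 6), and luminal and estrogen response genes 8.33 ± 1.53 of 20 against 5 ± 3.58 (FOXA1, a pioneer factor, 3 of 3 and 2 of 6). Cell cycle genes numbered 16.7 ± 1.15 of 18 against 11.7 ± 4.97 (MKI67, 3 of 3 and 1 of 6), HOXA genes 7.33 ± 0.577 of 11 against 5 ± 3.52, and ribosomal protein genes 21.7 ± 0.577 of 22 against 14.8 ± 6.88. Basal and mesenchymal genes numbered 10 ± 0 of 17 against 5.83 ± 3.66 (KRT14, a basal keratin, 3 of 3 and 1 of 6), and genes of other tissues 1.33 ± 1.53 of 20 against 0.833 ± 0.983. By the exact permutation test 0 of 14 lists passed after adjustment and 1 had an unadjusted p under 0.05.

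The mutant libraries had a larger part of their peaks at gene ends, at 37.0% ± 9.49 (SD, n = 3) for Flag-AF9F28R and 36.5% ± 8.55 (n = 3) for Flag-AF9G77A against 26.7% ± 4.56 (n = 3) for Flag-AF9WT. The differences of Flag-AF9WT were -10.3 and -9.81 points, each with an exact permutation p of 0.3 and an adjusted p of 0.375. Within batches the shares were 30.4% for Flag-AF9WT, 45.7% for Flag-AF9F28R and 41.7% for Flag-AF9G77A in the first, 21.6% and 41.2% for Flag-AF9WT and Flag-AF9G77A in the second, and 28.1% and 38.4% for Flag-AF9WT and Flag-AF9F28R in the third. With the same number of peaks in all lists but Flag-vector the differences turned to 11.5 and 21.8 points. With only peaks of -log10 q of at least 5 they were -4.43 and 0.654, and at 1 depth -1.46 and 2.03. The difference from Flag-AF9F28R was -5.90 without its replicate 1, and that from Flag-AF9G77A -14.7 without its replicate 3.

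Several groups of genes were occupied by AF9 above other genes, and differences between proteins or marks were not tested here. Ribosomal protein genes had gene-end peaks at 22 of 22 members in AF9 (adjusted p = 1.93e-06 by Fisher's exact test), Flag-AF9WT, Flag-AF9F28R and H3K9ac, and cell cycle genes at 16 of 18 in AF9 (adjusted p = 0.00141). Genes for AF9 partners and related complexes, a list that includes MLLT3 itself, had peaks at 18 of 20 members in AF9 (adjusted p = 0.000842 by Fisher's exact test). Peaks lay at 16 of 20 in Flag-AF9WT (adjusted p = 0.0498 by Fisher's exact test) and 20 of 20 in Flag-KLF2 (adjusted p = 1.93e-05) and H3K9ac. Glycolysis and lactate genes had peaks at 16 of 21 members in AF9 (adjusted p = 0.0296 by Fisher's exact test) and 18 of 21 in Flag-KLF2 (adjusted p = 0.00368), and acyl writers and erasers at 16 of 19 in AF9 (adjusted p = 0.00419). By Fisher's exact test Flag-KLF2 did not pass for ribosomal protein genes (11 of 22, adjusted p = 1) or cell cycle genes (11 of 18, adjusted p = 0.666). By the same exact test H3K9la did not pass for AF9 partners (13 of 20, adjusted p = 0.197), acyl writers and erasers (13 of 19, adjusted p = 0.169) or glycolysis and lactate genes (15 of 21, adjusted p = 0.0562). In the exact test Flag-AF9F28R did not pass for acyl writers and erasers (14 of 19, adjusted p = 0.0657), and Flag-AF9G77A passed for cell cycle genes alone, with ribosomal protein genes at 9 of 22 (adjusted p = 0.0777). Genes of other tissues were the low group, with 1 of 20 in AF9, Flag-AF9WT, Flag-AF9F28R and H3K9la and 5 of 20 in H3K9ac. In AF9, KLF family genes had peaks at 9 of 17 members, EMT and invasion genes at 14 of 22, epithelial adhesion genes at 7 of 18, metastasis suppressors at 10 of 16 and luminal and estrogen response genes at 7 of 20. KLF2 targets known from other cells had peaks at 6 of 15, HOXA genes at 5 of 11 and basal and mesenchymal genes at 8 of 17, and none of these 8 lists passed in any group. Of 112 tests 30 passed, 25 with more members than other genes and 5 with fewer. These tests run over genes, which are not independent replicates, and hold no spread between libraries. Among genes with an H3K9ac gene-end peak 0 of 98 tests passed by Fisher's exact test, 11 had an unadjusted p under 0.05 and the lowest adjusted p was 0.109. With the same number of peaks in all lists but Flag-vector 11 of the tests against all genes passed.

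Flag-KLF2 and AF9 shared most of their genes. Of 9772 genes with a Flag-KLF2 gene-end peak, 7325 (75.0%) also had an AF9 peak, where independent placement gives 4477. Among genes with H3K9ac, Flag-KLF2 was at 80.3% of AF9 genes and 51.4% of other genes, and among genes without H3K9ac at 39.6% and 11.8%. The odds ratio within H3K9ac strata was 3.87 (95% interval 3.54 to 4.22) for AF9, 2.63 (2.38 to 2.91) for Flag-AF9WT and 2.85 (2.62 to 3.10) for H3K9la. For AF9 it was 7.29 with the same number of peaks in all lists but Flag-vector, outside the interval. There were 4661 genes with a peak in every AF9, Flag-AF9WT, Flag-KLF2 and H3K9la library and in no Flag-vector library. The 10 strongest of them were ACSS2, which makes acetyl-CoA from acetate, TMEM141, SEPTIN10 and SOWAHC, which share a peak, RRM2B, a ribonucleotide reductase subunit, EEF2KMT, CD55, a complement regulator, ZBTB3, SLC2A8, a glucose transporter, and CDCA2. They ranked at mean percentiles from 98.6 (CDCA2) to 99.2 (ACSS2) of -log10 p. By region the overlap was smaller, at 37.2% of Flag-KLF2 regions in AF9 regions and 44.7% of AF9 regions in Flag-KLF2 regions, against 1.44% and 1.71% after circular shifts. Genes are not independent replicates, and the 2 Flag-KLF2 libraries came from separate batches.

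Set against Flag-AF9WT, Flag-KLF2 differed at genes in both directions. It held 1194 genes in both of its libraries and in no Flag-AF9WT library, led by WNT3A, a Wnt ligand (chromosome 1, 228006998 to 228061271), TMEM278, COL6A1, a collagen VI chain, SLC17A7, a vesicular glutamate transporter, PRG3, MRGBP, SMIM24, IGFALS, DEGS2 and ZFPM1, all at mean percentiles from 98.0 to 99.6. The reverse held for 998 genes, led by SCAF11, NBN, a DNA repair gene (chromosome 8, 89933331 to 89984667), PLAUR, the urokinase receptor, UQCRB, BIRC2, ZNF91, NDUFB4, PRSS12, EID1 and SSR3. Among list members, the endothelial nitric oxide synthase gene NOS3, a textbook KLF2 target, TIMP2, MMP9, ESRP1, MYB, ENO2, KAT2A, KLF8, INS and GFAP had a peak in 2 of 2 Flag-KLF2 and 0 of 3 Flag-AF9WT libraries. EDN1, another KLF2 target, SNAI2, TGFBR2, LOX, RPL11, RPL19, RPL32, SLC16A3, MCM3, HOXA11, KRT14 and PDZK1 had a peak in 0 of 2 and 3 of 3. Only gene ends were counted, so a peak at a promoter well between them is not seen here. Ribosomal protein genes numbered 15 ± 2.83 of 22 in Flag-KLF2 (n = 2) and 21.7 ± 0.577 in Flag-AF9WT (n = 3), and genes of other tissues 6.5 ± 2.12 of 20 and 1.33 ± 1.53. Without Flag-KLF2 replicate 1 the counts of genes were 1857 and 1221, and without replicate 2 they were 1270 and 1772. At 1 depth they were 1868 and 364, and with the same number of peaks in all lists but Flag-vector 592 and 1228.

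A Flag-KLF2 library overlapped 51.1% ± 0.372 (SD, n = 2) of AF9 regions, 23 points below Flag-AF9WT, with an exact permutation p of 0.1 and an adjusted p of 0.25. Its gene-end share of peaks was 26.3% ± 1.4 (n = 2), which differed from Flag-AF9WT by -0.425 points (exact p = 0.9, adjusted 0.9). That difference was -8.62 with only peaks of -log10 q of at least 5, -28.1 with the same number of peaks in all lists but Flag-vector, -10.4 at 1 depth and 2.07 with a 2.5 kb window. It was 1.43, -2.97 and 0.273 without Flag-AF9WT replicates 1, 2 and 3, and -1.42 and 0.570 without Flag-KLF2 replicates 1 and 2, so its direction was not settled. No batch held both groups, so group and batch cannot be told apart. With only peaks of -log10 q of at least 5 Flag-KLF2 lay 15.1 points below in AF9 regions, and at 1 depth the direction turned. Of the AF9 regions of the full lists, thinned Flag-KLF2 libraries held 43.8% and 36.6% and thinned Flag-AF9WT libraries 32.7%, 33.1% and 42.4%.

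The marks H3K9la and H3K9ac covered much of the same ground, with H3K9ac the wider. Of 27057 H3K9la regions 78.7% overlapped H3K9ac regions, and of 35383 H3K9ac regions 58.9% overlapped H3K9la regions, against 2.09% and 1.60% after circular shifts. A library of H3K9la had 65.9% ± 5.23 (SD, n = 3) of its peaks in H3K9ac regions, and a library of H3K9ac had 49.2% ± 0.398 (n = 3) of its peaks in H3K9la regions. Regions with H3K9la alone lay at gene ends in 3.13% of cases, regions with H3K9ac alone in 22.5% and regions with both in 34.0%. At genes, 1472 had a gene-end peak in every H3K9ac library and in no H3K9la library, and 2 the reverse, CPLX2 and CATSPER2. With the same number of peaks in all lists but Flag-vector the counts were 791 and 81. The strongest of the 1472 were SCAF11, GPR61, UQCRFS1, a subunit of respiratory complex III, PRSS12, ZNF302, PLAUR, E2F4, a cell cycle repressor, ARL8A, SNRPB2 and WDR45B, at mean H3K9ac percentiles from 94.4 to 99.5. The reverse numbered 25 without H3K9la replicate 2, 24 without H3K9la replicate 3, 16 without H3K9ac replicate 3 and 11 without H3K9la replicate 1. The 1472 became 2221 without H3K9la replicate 1, and the real grouping is 1 of 10 possible splits. Within the first batch 2801 genes had H3K9ac and no H3K9la and 402 the reverse, and in the undated set, with 1 H3K9ac and 2 H3K9la libraries, 2749 and 26.

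By list, HOXA genes had gene-end peaks at 3.67 ± 1.15 of 11 members in H3K9la and 9 ± 0 in H3K9ac (SD, n = 3 each), with HOXA9 and HOXA11 in 0 of 3 and 3 of 3 libraries. Epithelial adhesion genes numbered 5.33 ± 0.577 of 18 and 11.7 ± 0.577 (KRT18, a luminal keratin, ESRP2 and CLDN7, 0 of 3 and 3 of 3). AF9 partners numbered 13.3 ± 1.53 of 20 and 19.7 ± 0.577 (MLLT1, the paralog of AF9, BCOR and the H3K79 methyltransferase gene DOT1L, 0 of 3 and 3 of 3), and ribosomal protein genes 16.3 ± 1.53 of 22 and 22 ± 0 (RPL19, RPS2 and RPL3, 0 of 3 and 3 of 3). CCND1 and BCL2, luminal genes, KLF9, KLF16, PFKL, AARS2, SIRT3, TWIST2 and PLK1 also stood at 0 of 3 and 3 of 3. EDN1, an endothelin gene, stood at 2 of 3 and 0 of 3. Its annotated ends lie at 12230516 and 12297194 of chromosome 6, and a promoter well between them was not covered. All genes with a gene-end peak numbered 8940 ± 732 per H3K9la library and 12115 ± 120.5 per H3K9ac library (SD, n = 3 each). Lower counts in H3K9la were therefore general, and a lower count in a list is not by itself a trait of that list. These list counts were not tested between the marks. The share of H3K9la regions in H3K9ac regions ran from 67.5% to 88.6% when single libraries were left out, and was 45.7% with the same number of peaks in all lists but Flag-vector.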

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

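Both tests of the MLLT3 peaks were chosen only after the peaks were seen. The values here stood out as signal in data that no comparison used, since the peaks lie inside the gene that a construct encodes and are absent from the Flag-vector lists. No group held 4 or more libraries, so no library was tested for lying apart from its group.

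Inside MLLT3 (chromosome 9, 20341669 to 20622499), the gene of AF9, the highest -log10 p was 11344.6 in Flag-AF9F28R replicate 3 and 12602.8 in Flag-AF9G77A replicate 3, each with 10 peaks above 100 and widths of 537 to 1045 bp. Binding of AF9 to its own gene is argued against, since 0 of these 10 positions had a peak in any of the 10 other AF9, Flag-AF9WT and mutant lists. Flag-AF9F28R replicate 2, with none, was as deep as replicate 3 (background pileup 0.554 and 0.509), so binding shared by libraries of a mutant is argued against too. All 100% of the positions had both ends within 50 bp in the 2 libraries, and no AF9, H3K9la, H3K9ac or Flag-vector list held one above 100, which is consistent with DNA of the expression construct. Against it stand the 3 Flag-AF9WT lists and the 4 other mutant lists, which name constructs of the same gene and held 0 of the positions. These 2 libraries also shared 21 peaks above 300 outside MLLT3 with Flag-KLF2 replicate 1 alone. All 3 libraries are of the undated set and name a Flag construct, so the 21 peaks do not decide the question. DNA of the construct stays an open hypothesis, because the gene table holds no exons against which the positions could be compared. All results stayed in their class without peaks at MLLT3 and KLF2.

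In Flag-KLF2 replicate 2 the highest -log10 p inside MLLT3 was 23.4, and 4 of the 10 positions had a peak. Inside KLF2 (chromosome 19, 16324826 to 16328685) the highest -log10 p was 12644.5 in Flag-KLF2 replicate 1 and 10973.9 in Flag-KLF2 replicate 2, each the strongest peak of its list, with a further peak at 1649.73 and 882.538. No explanation was tested for the KLF2 peaks.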

How the results depend on the processing

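Leaving out replicate 3 of both mutants, thinning every list but Flag-vector to 1 depth, leaving out peaks at MLLT3 and KLF2, and using the gene end with the stronger H3K9ac peak were tests chosen only after the results were seen. Outside the leave-one-out settings, 207 values stayed in their class, 34 moved and 20 reversed. The class of a tested difference is its direction and side of the threshold, whatever its size, so many of the 207 changed size. Untested shares had to stay within 1 SD, and counts within 1.5 times. Overlap over 50% of the shorter region, all sequences, unmerged peaks, leaving out MLLT3 and KLF2 peaks, and the H3K9ac-marked end changed none of the results they were run on. Overlap over 50% was not run for counts of regions, where a union region has no single shorter partner, and the KLF motif alternatives and the window at the starts of all transcripts were not run. No permutation test passed after adjustment under any of these settings, and with 3 libraries against 3 none can, so those p-values say nothing about stability. Depth limits every count of absent peaks, since a list of a shallow library omits weak sites.

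With only peaks of -log10 q of at least 5, regions in every Flag-AF9WT library and none of Flag-AF9F28R, Flag-AF9G77A or either mutant numbered 792, 2145 and 666, the gene-end share of Flag-AF9WT minus Flag-AF9G77A was 0.654, and the shares of H3K9la regions in H3K9ac regions and the reverse were 84.2% and 50.5%. The cause was not tested.

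With the same number of peaks in every list but Flag-vector, the share of AF9 regions in Flag-AF9WT differed by -10.2 from Flag-AF9F28R, -3.05 from Flag-AF9G77A and -6.61 from both. The shares of H3K9la and H3K9ac regions stayed higher in Flag-AF9WT, by 5.61 and 19.2 against both (permutation p = 0.0476 and 0.0119, adjusted 0.12 and 0.0714). H3K9la-alone minus H3K9ac-alone regions gave 22.4 for AF9 and -10.7 for Flag-AF9WT. Flag-AF9WT-only regions and the reverse numbered 264 and 208 (Flag-AF9F28R), 510 and 343 (Flag-AF9G77A), and 189 and 97 (both). Gene-end differences were -30.6 for AF9 minus H3K9ac, and 11.5 and 21.8 for Flag-AF9WT minus Flag-AF9F28R and Flag-AF9G77A. Passing lists numbered 11, and the shares between the marks were 45.7% and 41.7%. By construction this setting removes most peaks of the long lists.

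With vector peaks removed, Flag-AF9G77A-only and mutant-only regions numbered 24 and 4, and the share of H3K9ac regions in H3K9la regions was 58.3%. With regions required in every library the shares between the marks were 84.9% and 50.6%. With a gene-end window of 2.5 kb the gene-end share of Flag-KLF2 minus Flag-AF9WT was 2.07, and with a replicate block it was 0.273 (permutation p = 1). No other difference changed direction or side of the threshold under the replicate block, which was not run for regions, genes or lists. The cause was not tested.

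Without the replicate 3 libraries of both mutants, Flag-AF9WT-only regions and the reverse numbered 4746 and 47 (Flag-AF9F28R), 13538 and 67 (Flag-AF9G77A), and 4659 one way (both); fewer libraries have to lack the region.

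With every list but Flag-vector thinned to 1 depth, peaks per library differed by -2607 from Flag-AF9F28R and -1090 from both. The regions were called again from the thinned lists. The share of AF9 regions differed by -13.9, -0.445 and -7.19 from Flag-AF9F28R, Flag-AF9G77A and both, and by -4.12 from Flag-KLF2, which was then the higher. The share of H3K9la regions differed by -9.91 from Flag-AF9F28R and -3.12 from both, and that of H3K9ac regions by -7.10 from Flag-AF9F28R. Flag-AF9WT-only regions and the reverse numbered 144 and 414, 265 and 238, and 85 and 109. Gene-end differences were -12.9 for AF9 minus H3K9ac and 2.03 for Flag-AF9WT minus Flag-AF9G77A, and the shares between the marks were 64.5% and 37.6%. By construction this setting removes the weaker peaks of deep libraries.

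Leaving out each library in turn, 245 values stayed in their class, 31 moved and 4 reversed. The share of AF9 regions in Flag-AF9WT minus Flag-AF9F28R ran from -1.58 (without Flag-AF9F28R replicate 1) to 28.6, that of H3K9la-alone minus H3K9ac-alone regions in AF9 from -15.2 to 9.25, and the gene-end share of Flag-KLF2 minus Flag-AF9WT from -2.97 to 1.43. Flag-AF9WT-only regions ran from 2201 to 4746 and the reverse from 36 to 509 (Flag-AF9F28R), from 4425 to 13538 and 46 to 157 (Flag-AF9G77A), and from 1894 to 4073 and 7 to 14 (both), with 13538 without Flag-AF9G77A replicate 3, 4746 without Flag-AF9F28R replicate 3, and 509 without Flag-AF9F28R replicate 1. The shares between the marks ran from 67.5% to 88.6% and from 43.6% to 64.5%.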

Other observations

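The tests of batches, and of depth and enrichment for the H3K9ac-only genes, were chosen only after the results were seen. The depth tests of the mutants and the counts over other splits were fixed beforehand.

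Flag-KLF2 held many regions outside AF9 and both marks. Of its 27399 regions, 12872 (47.0%) overlapped no AF9, H3K9la or H3K9ac region, and of these 55.2% lay in gene bodies, 34.5% outside genes and 10.4% at gene ends. Of the 14527 that overlapped any, 49.7% lay at gene ends. Of the 1194 genes with a peak in both Flag-KLF2 and no Flag-AF9WT library, 372 (31.2%) had H3K9ac at a gene end, against 980 of 998 (98.2%) of the genes with the reverse. Genes of other tissues had gene-end peaks at 6.5 ± 2.12 of 20 members in Flag-KLF2 (SD, n = 2), 5 ± 1 in H3K9ac (n = 3) and 1.33 ± 0.577 in AF9 and H3K9la (n = 3 each). The insulin gene INS and the glial gene GFAP had a peak in 2 of 2 Flag-KLF2 libraries. No vector library shared a batch with Flag-KLF2, and no explanation of these regions was tested.

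Flag-AF9F28R replicate 3, Flag-AF9G77A replicate 3 and Flag-KLF2 replicate 1, all of the undated set, shared 21 peaks with -log10 p above 300 that were in none of the 19 other lists. The strongest lay inside TBC1D5 at chromosome 3, 17401781 to 17402491, with -log10 p of 6505 in Flag-AF9F28R replicate 3. Others lay inside FAR2, ILDR2, FAT3, TNIK, FRZB, GULP1 and SLC18A1, genes named after their values were seen.

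Replicates 1 and 2 of both mutants held fewer AF9 regions than Flag-AF9WT, while replicate 3 of both held as many. For Flag-AF9G77A, lower depth as the whole cause is argued against, since it held 0.437 and 0.602 times the AF9 regions of the Flag-AF9WT list of its batch thinned to its depth, and a batch difference is argued against by a share in Flag-AF9WT at least 3.25 times as high within both batches. For Flag-AF9F28R the thinned ratios were 0.758 and 0.875 and the lower within-batch ratio was 1.23. Batch does not differ within a pair, but a ratio of 1.23 left its part in the group difference undecided. Depth and mutation cannot be told apart with these pairs. Replicate 3 came from a set with 0 Flag-AF9WT libraries, whose AF9, H3K9la and H3K9ac lists also held more peaks at 1 depth (21411 and 22463 against 14022 for AF9), so batch and mutation cannot be told apart there. A lower occupancy of AF9 sites by the G77A mutant in replicates 1 and 2 may remain as a hypothesis, with protein level and yield of the reaction untested.

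Over the splits of the libraries, the counts of regions in every library of one side and none of the other were set against the real grouping. For Flag-AF9WT against Flag-AF9F28R, 1 of 10 splits, the real one, reached its 2214 regions and the highest other gave 1342. For Flag-AF9G77A it was again 1 of 10, with 4431 and 1753, and in both cases the splits are too few for a share under 0.05. Against both mutants 2 of 84 splits reached 1901 regions, a share under 0.05, but the splits exchange libraries across batches, and the 12 arrangements within batches cannot give a p under 0.0833. Chance was therefore not excluded for this grouping. The larger count, 5273, came from the split that set Flag-AF9F28R replicate 1 and Flag-AF9G77A replicates 1 and 2, the 3 libraries of lowest depth, against the rest.

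Genes with H3K9ac and no H3K9la at a gene end numbered 1472 and the reverse 2. Lower depth of the H3K9la libraries as the whole cause is argued against, since at 1 depth the counts were 1872 and 4, a ratio of 468. With the same number of peaks in all lists but Flag-vector the imbalance was smaller, at 791 and 81. Weaker enrichment in the H3K9la libraries is consistent with a median H3K9ac percentile of 68.5 for these genes and 90.7 for the 6921 genes in all 6 libraries, a difference of -22.2 points, since the weaker sites would be lost first. A lack of lactylation at these genes stays open and was not tested apart from it. For the sum of 1474 genes 1 of 10 splits reached the real count, the highest other gave 40, and the splits are too few for a share under 0.05.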
